A study of Mus musculus with 2 samples.

How the data were processed

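Messenger RNA of single cells or nuclei from the locus coeruleus (LC) of wild-type C57BL/6N mice was counted with droplet libraries of the 10x Genomics Chromium system. The labels give 2 libraries, batch 1 and batch 2, of 1 group of mice aged 3 to 4 weeks and of both sexes, and the series text calls them independent samples. Batch and replicate are therefore the same thing, and the labels give neither the number of mice per library nor the pooling. The labels describe 2 protocols, papain dissociation of slices followed by methanol fixation and isolation of nuclei with a 7-AAD sort, without saying which library came from which. The word cell below stands for either.

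The deposited matrices hold counts, 1 whole number of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. The submitters' notes name Cell Ranger 7.0, Seurat and the builds mm10 and GRCm38, while per the file headers the matrices of counts came from Cell Ranger 6.1.2. Whether intronic reads were counted is not stated in these sources. No barcode had fewer than 500 UMIs in library 2 or 4208 in library 1, so cells had been called before deposit, at a different depth in each library. Of the 32285 features, 32158 (99.61%) were found in the GENCODE M21 annotation of GRCm38, which gave positions and lengths.

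Cell classes, comparisons, gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. Barcodes with at least 300 detected genes and at most 20% mitochondrial UMIs were kept. In each library the highest Scrublet doublet scores were then removed, at a rate of 0.8% for every 1000 barcodes. Counts were scaled to 10000 per cell and log-transformed with scanpy 1.11.5 (anndata 0.12.19, Python 3.11.15). Clusters came from 143 cell type marker genes in 25 lists and from no other gene: 20 principal components, 15 neighbours, Leiden resolution 1.0 (igraph 0.11.9) and seed 1. The libraries were not integrated. A cluster was neuronal where the 10 pan-neuronal markers summed to at least 5000 CPM (UMIs of a gene over all UMIs of the class or cluster, on the usual CPM scale). It took a class name where at least 3 markers of a list, each at 10 CPM or more, lay at a log2 ratio of 2 or more over the median cluster (prior 20 CPM), and where no other list came within a log2 of 1. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. So did a shallow cluster with no marker of its own class there, and all remaining clusters. The marker lists were pan-neuronal, noradrenergic, inhibitory, excitatory, serotonergic, cholinergic, mesencephalic trigeminal, cerebellar granule, Purkinje and immature neurons, astrocytes, oligodendrocytes, their precursors and committed precursors, ependymal and choroid plexus cells, microglia, border macrophages, other leukocytes, endothelial, mural, fibroblast, erythroid and Schwann cells, and dividing cells. Committed precursors shared the name of oligodendrocytes and so could not be named apart. Microglia and border macrophages shared a name, as did endothelial, mural, fibroblast and erythroid cells. Lists sharing a name did not exclude each other. In the main setting no cluster took the name of serotonergic, cholinergic, Purkinje or immature neurons, or of Schwann, choroid plexus or dividing cells. Purkinje (19 and 81 cells), cholinergic (3 and 26) and immature neurons (1 and 58) took names with at least 500 genes, Purkinje (11 and 53) and cholinergic neurons (3 and 71) at resolution 2.0, and cholinergic neurons (2 and 21) with 2 times the doublets removed. Class names mean that the summed counts of the clusters carried those markers. Numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.

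For each comparison the UMIs of each class were summed per library. The 4 sums were compared with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), two-sided, with TMM normalization, the low-count filter filterByExpr and the library as a block, since both classes of a comparison were drawn from each library. Adjusted p values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold for a call, and a class needed at least 5 cells in each library. The fit leaves 1 residual degree of freedom, so spread is shared across genes. With the library as a block, the p values measure how the difference between 2 classes varied between the libraries. This spread may be technical and does not extend to spread between mice. Because it is shared across genes, a gene could be called although its own folds in the 2 libraries differed. Standard errors (SE) of log2 folds were taken as the fold over the square root of F, so they rest on the same shared spread. Folds of single libraries are log2 CPM differences with a prior count of 2, which pulls folds of scarce genes toward 0. A gene with no UMI in 1 class has a bound against 3 counts over both libraries in place of a fold, and a gene with 1 to 3 UMIs there has a pooled ratio with its exact 95% interval. Data simulated with the sums' depths and the same dispersion for every gene were tested the same way. Genes with a spread of their own were not simulated, so the shares and false calls below may not hold for the real data. In the comparison of noradrenergic-like cells with other neurons, 46.3% of genes simulated at a log2 fold of 1 and 88% of those at 2 were called, with 7 unchanged genes called. The same shares were 18.6% and 86.6% against non-neuronal cells, 50% and 97% between inhibitory and excitatory neurons, and 44.3% and 95.9% between galanin-high and galanin-low cells.

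The 12 outcome lists, with 265 genes, were neuropeptide precursors, neuropeptide receptors, peptide processing and granins, tetrahydrobiopterin and monoamine metabolism, adrenergic receptors, GIRK channels and gap junctions, pacemaker and calcium channels, glutamate and GABA receptors, growth factors and receptors, transcription factors of hindbrain neurons, dissociation response, and nuclear RNA. Genes named in a comparison are the 10 largest log2 folds in each direction among called genes with the same sign in both libraries and at least 50 CPM in the higher class of each, without markers, mitochondrial or predicted genes. Gal, Galr1, Galr2, Galr3, Npy and Cartpt are named in addition, with up to 4 members per list: the called ones of highest level in the first class or, where fewer than 2 were called, the highest expressed ones. For levels, the 10 precursors and 10 receptors of highest mean CPM in noradrenergic-like cells are named, with Gal and its receptors. Any other gene was chosen after its values were seen.

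Levels are CPM of class sums, as a mean of the 2 libraries with equal weight and their standard deviation (SD). Shares of cells with a UMI were taken after thinning each cell at random to 1000 UMIs, with exact Clopper-Pearson 95% intervals. A share of 0 is given the limit of 3 counts of the total. Intervals and limits cover counting error only. The libraries were compared within classes for genes with at least 20 UMIs, as log2 ratios with 5 CPM added, and the median of each list was ranked among 10000 random lists of the same size matched on level. Highest classes were read among named classes with at least 5 cells in each library. A gene was counted where the same class led in both libraries and its mean level there was 20 CPM or more.

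Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, no low-count filter, no replicate block, all classes in 1 fit, each library left out, at least 500 genes, at most 10% mitochondrial UMIs, no doublets or 2 times the doublets removed, Leiden resolutions 0.5 and 2.0, 2000 highly variable genes without the outcome lists in place of markers, a class defined by UMIs of 3 noradrenergic markers, and thinning to 500 or 2000 UMIs. Thinning to 5000 UMIs, leaving out trigeminal and granule neurons, leaving out a galanin-low cell of library 1 that held Gad2, and the comparisons of trigeminal neurons and of an unnamed cluster were added after the data had been seen. A test that left out 2 cells, and results of some genes, are not reported here. Nothing deposited was left out apart from the 65 barcodes that failed the filters and the 64 removed as doublets.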

Results

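The series measured RNA in single cells or nuclei of the mouse locus coeruleus (LC), the pontine nucleus that supplies most of the noradrenaline of the forebrain, and its title asks about the diversity of peptide signalling there, galanin included. Both libraries, batches 1 and 2, came from wild-type C57BL/6N mice of both sexes aged 3 to 4 weeks, so there was 1 group with n = 2 and comparisons ran between cell classes within each library. Library 1 held 304 barcodes with 5600693 UMIs (median 11010 per barcode), and library 2 held 2796 barcodes with 6895380 UMIs (median 1517). After filtering, 294 and 2677 cells remained. These 2971 cells compare with 2578 stated by the series. Of them 2555 had at least 500 detected genes, and the filter behind the stated number is not given.

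Neurons were 67.7% of the cells in library 1 (exact 95% interval 62.0 to 73.0) and 45.4% in library 2 (43.5 to 47.3). Noradrenergic-like cells numbered 12 (4.08%, 2.13 to 7.02) and 77 (2.88%, 2.28 to 3.58). Their summed counts held all 8 markers of their list at 10 CPM or more. Among these were the dopamine beta-hydroxylase gene Dbh and the noradrenaline transporter gene Slc6a2, each without a UMI in 1 or more cells of library 2. The other neurons were excitatory-like (76 and 293 cells), inhibitory-like (35 and 240), cerebellar granule-like (37 and 49), mesencephalic trigeminal-like, the proprioceptive jaw muscle neurons that lie beside the LC (11 and 39), and unnamed (28 and 517). An unnamed cluster of 2 and 143 cells counted as neurons had macrophage genes such as Cd86 among its leading genes, but its pan-neuronal markers summed to 17210 CPM against 4072 in the microglia or macrophage-like cluster. Non-neuronal cells were oligodendrocyte-like (37 and 657), astrocyte-like (16 and 316), ependymal-like (19 and 98), vascular or blood-like (10 and 207), oligodendrocyte precursor-like (11 and 80), microglia or macrophage-like (1 and 31) and unnamed (1 and 73). The lowest deposited barcode had 4208 UMIs in library 1 and 500 in library 2, so the shares were not compared between the libraries.

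Noradrenergic-like cells held far more RNA than their neighbours: a median of 83596.5 UMIs in library 1 and 7813 in library 2, 6.05 and 3.59 times the medians of the other neurons (13824 and 2177). Trigeminal-like neurons also stood out, with medians of 60464 and 12384 UMIs (4.37 and 5.69 times). Oligodendrocyte-like cells had 9760 and 1407 UMIs.

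**Figure D1:**
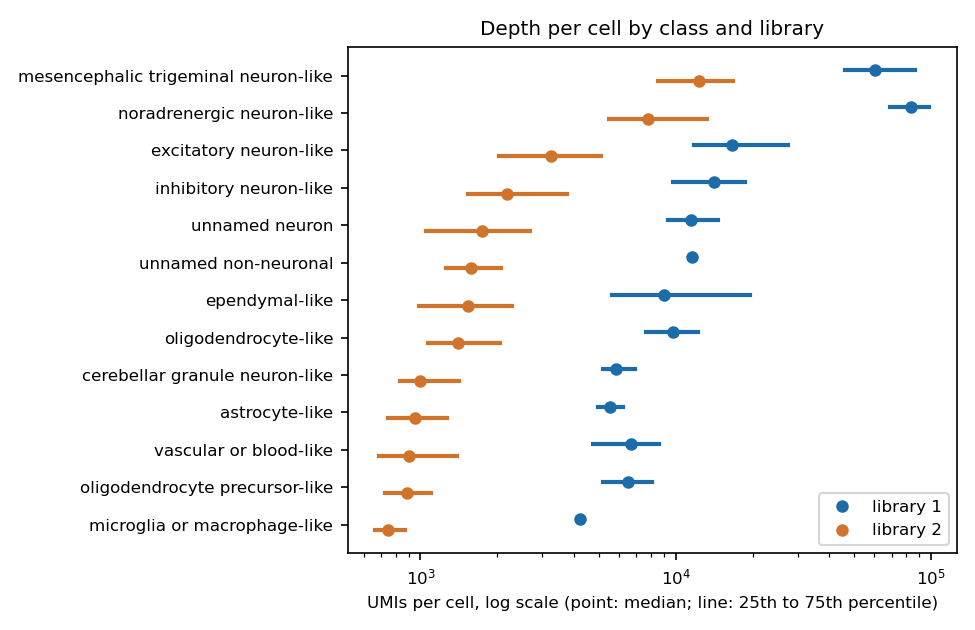
UMIs per cell (log axis) of each cell class in library 1 and library 2, with points at the median and lines from the 25th to the 75th percentile. Noradrenergic-like and mesencephalic trigeminal-like neurons lie above every other class in both libraries, with medians of 83596.5 and 7813 UMIs for noradrenergic-like cells.

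Noradrenergic-like cells were first set against all other neurons, to ask which transcripts set LC neurons apart from the neurons around them. Gal, the gene of the neuropeptide galanin (ENSMUSG00000024907, GRCm38 chromosome 19, 3409915 to 3414544, minus strand), gave the largest rise of the named genes, from 2.8 and 1.1 CPM in other neurons to 587 and 247 CPM in libraries 1 and 2 (log2 fold 7.66 ± 0.24, SE, n = 2, adjusted p 2.1e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc10a4, a synaptic vesicle protein of monoamine and acetylcholine neurons, rose by 5.33 ± 0.22 log2 units, the lectin gene Chodl by 5.33 ± 0.28, and Maoa, a monoamine-degrading oxidase, by 4.61 ± 0.17. Further rises were Fibcd1 (4.04 ± 0.25), Gch1, of amine cofactor synthesis (4.03 ± 0.26), Calca (3.97 ± 0.24), the calcitonin receptor gene Calcr (3.83 ± 0.20), the orexin receptor gene Hcrtr1 (3.75 ± 0.34) and Cd24a (3.55 ± 0.27). Several transcripts of other neurons were nearly missing: no UMI of Bnc2, Pth1r or Foxp2 was seen in the class, which puts them at least 55.5-fold, 50.4-fold and 37.0-fold lower. Tafa1 fell by 6.49 ± 0.28 and Caln1 fell by 6.23 ± 0.35 log2 units. The pooled ratios of genes with 1 or 2 UMIs in the class were 0.0062 for Hs3st2 (95% interval 0.0002 to 0.0345), 0.006 for Pvalb (0.0002 to 0.0335), 0.0105 for Gfra1 (0.0013 to 0.0382), 0.0138 for Runx1 (0.0017 to 0.05) and 0.015 for Plpp4 (0.0018 to 0.0544). Of the 11644 genes tested, 1937 were higher and 1907 lower, 932 and 1266 of them by at least 2-fold, and 99.9% of calls had the same sign in both libraries. Calls came from both libraries together, so this share, here and in the comparisons below, is no independent replication.

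Peptide genes moved in both directions. Of 19 neuropeptide precursors tested, 9 rose and 5 fell (9 and 5 adjusted over the list alone), and 5 did not pass. Calca, the gene of calcitonin gene-related peptide (chromosome 7, 114631478 to 114636357, minus strand), stood at 231 and 82.8 CPM against 16.4 and 3.6. Cartpt, of the CART peptide, rose by 3.96 ± 0.43 and Nucb2, the nesfatin precursor gene, by 1.39 ± 0.26. Pdyn, Pomc, Agrp, Edn3 and Npb rose as well, and Tac1, Penk, Pnoc, Sst and Nps fell. Of 21 neuropeptide receptors, 7 rose and 7 fell (7 and 9 adjusted over the list alone) and 7 did not pass. The mu opioid receptor gene Oprm1 rose by 1.52 ± 0.32 and the PACAP receptor gene Adcyap1r1 by 0.96 log2 units, while Cckar, Cckbr, Oprk1, Crhr1, Trhr, Hcrtr2 and Prlr fell. Galr1, the galanin receptor gene of highest level (chromosome 18, 82392380 to 82406777, minus strand), stood at 4.0 and 2.8 CPM against 8.6 and 9.3 in the other neurons and did not pass (log2 fold -1.39 ± 0.58, adjusted p 0.0765 by edgeR). When trigeminal and granule neurons were left out of the other neurons, a setting chosen after the data were seen, Galr1 (-1.79), Npsr1 (-2.54) and Tacr3 (1.10) passed, and Cckar and Cckbr had too few counts to be tested. Of 13 peptide processing and granin genes, 4 rose (5 adjusted over the list alone) and 3 fell, with chromogranin B (Chgb) at 1.93 ± 0.18, Pcsk1n at 0.88 ± 0.14, Cpe at -0.61 and Cadps at -0.42.

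Genes of amine chemistry rose or did not pass. Of 8 genes of tetrahydrobiopterin and monoamine metabolism, 5 rose, none fell and 3 did not pass (6 rose adjusted over the list alone). They were Gch1, whose enzyme starts the cofactor's synthesis (chromosome 14, 47153895 to 47189413, minus strand, 94.1 and 103 CPM against 5.6 and 6.0), Pts, Qdpr, which recycles the cofactor (3.14 ± 0.18), Maoa (chromosome X, 16619698 to 16687818, plus strand, 818 and 532 CPM against 28.4 and 24.4) and Maob (2.39 ± 0.37). Of 4 adrenergic receptors, 1 rose and 3 fell, and the same genes passed adjusted over the list alone. Adra2a, the autoreceptor of LC neurons, rose to 42.5 and 45.5 CPM from 7.5 and 2.7 (3.05 ± 0.37, adjusted p 4.55e-06 by edgeR), Adra1a fell by 0.76 ± 0.27, Adrb1 was at least 3.71-fold lower, and the pooled ratio of Adra1b was 0.0325 (0.0008 to 0.184). Transcription factors of hindbrain neurons mostly fell, 9 of 13, while 1 rose (9 and 1 adjusted over the list alone). Tfap2b was the riser (1.87 ± 0.17), and Ebf1 (-3.86 ± 0.26), Zfhx3 (-2.22 ± 0.16) and Pbx3 (-0.53) were among those that fell.

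Channels and fast transmitter receptors were mixed. Of 19 pacemaker and calcium channels, 2 rose and 10 fell (2 and 12 adjusted over the list alone). The small-conductance potassium channel genes Kcnn3 (1.29 ± 0.17) and Kcnn2 (0.78 ± 0.15), which shape the pause after a spike, rose, whereas Hcn2, Hcn4, Cacna1a (-0.46) and Kcnq3 (-0.38) were among those that fell. Of 30 glutamate and GABA receptors, 7 rose and 12 fell (8 and 12 adjusted over the list alone), with Grin2a at 0.75, Gabrb1 at 0.73, Gabbr1 at 0.56 and the AMPA receptor gene Gria1 at -1.04 ± 0.15. Of 6 GIRK channel and gap junction genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Panx1 at 0.79, Kcnj9 at 0.61 and Kcnj3 at -0.63. Of 12 growth factors and receptors, 4 rose and 6 fell (4 and 6 adjusted over the list alone). Fgf13, an intracellular sodium channel partner, reached 1341 and 1287 CPM against 162 and 173 (2.92 ± 0.14), Vgf lay at 0.96, Bdnf at 0.94 and Ntrk3 at -0.57. Of 12 dissociation response genes, 1 rose (Jund, 0.58), 1 fell (Egr1, -0.57) and 10 did not pass. Of 5 nuclear RNAs only Mir9-3hg fell (at least 9.95-fold lower). Malat1 did not pass (-0.27 ± 0.14, adjusted p 0.168 by edgeR), except with no low-count filter (-0.36). Both lists had the same counts adjusted over the list alone.

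Under DESeq2, 1266 genes were called in place of 3844, and the calls of 21 of the 56 named genes ended: Bnc2, Pth1r, Nucb2, Adcyap1r1, Cadps, Cpe, Adra1a, Adrb1, Kcnj3, Kcnj9, Panx1, Cacna1a, Kcnq3, Gabbr1, Ntrk3, Vgf, Bdnf, Pbx3, Jund, Egr1 and Mir9-3hg. Those of Adra1b, Kcnn2, Gabrb1 and Grin2a ended where the class was defined by 3 markers, and the folds of library 1 and library 2 taken alone differed from each other for Cartpt (1.79 and 4.59), Oprm1 (2.39 and 0.37), Hcrtr1 (4.42 and 2.77), Chodl (5.73 and 4.39), Caln1 (-5.29 and -8.35), Ebf1 (-3.27 and -4.94), Adra2a (2.32 and 3.63), Adra1a (-1.36 and -0.23), Bdnf (0.28 and 1.56), Jund (0.01 and 1.11) and Fibcd1 (4.44 and 3.45). For Gal they were 7.28 and 6.91.

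**Figure D2:**
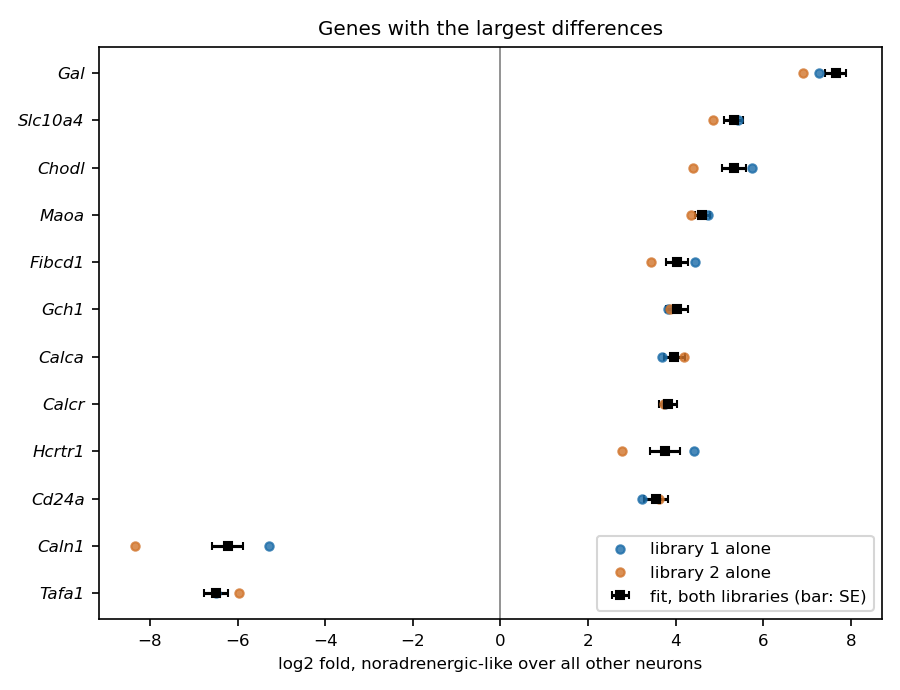
Log2 fold of noradrenergic-like cells over all other neurons for the genes with the largest differences and more than 3 UMIs in each class: edgeR fit (black squares, bars are SE, n = 2 libraries) and each library alone (coloured points). Gal lies highest at 7.66 and Tafa1 lowest at -6.49.

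The peptide signalling profile of the noradrenergic-like class was then read as levels. Gal was the precursor of highest level, at 417 ± 241 CPM (SD, n = 2 libraries), followed by Calca (157 ± 105), Cartpt (78.8 ± 91.4), the PACAP gene Adcyap1 (72.5 ± 28.1), Nucb2 (48.5 ± 10.1) and Pdyn (29.2 ± 21.2). Library 1 gave 14.2 CPM of Cartpt and library 2 gave 143. The corticotropin-releasing hormone gene Crh had 0 and 41.4 CPM, Agrp 15.5 ± 3.37, Grp 0 and 30.3, and Nppc 1.01 and 19.3. The Crh UMIs of library 2, 30 in number, came from 3 cells. Npy had 6 UMIs, all from 1 cell of library 2. Calcr was the receptor of highest level (206 ± 53.5 CPM; chromosome 6, 3685680 to 3764714, minus strand), followed by Oprm1 (86.6 ± 52.2), Adcyap1r1 (79.4 ± 10.8), Hcrtr1 (79.3 ± 28.2), the substance P receptor gene Tacr1 (59.8 ± 18.8), Sstr2 (44.1 ± 7.76), Agtr1a (29.0 ± 3.82), Npr2 (19.6 ± 3.44), Tacr3 (16.6 ± 7.73) and Oprl1 (16.5 ± 3.85). Galanin receptors were scarce: Galr1 had 3.40 ± 0.91 CPM, from 4 UMIs in library 1 and 2 in library 2, Galr2 had 1 UMI in library 1, and Galr3 had none, which allows up to 3.04 CPM in library 1 and 4.14 in library 2.

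**Figure D3:**
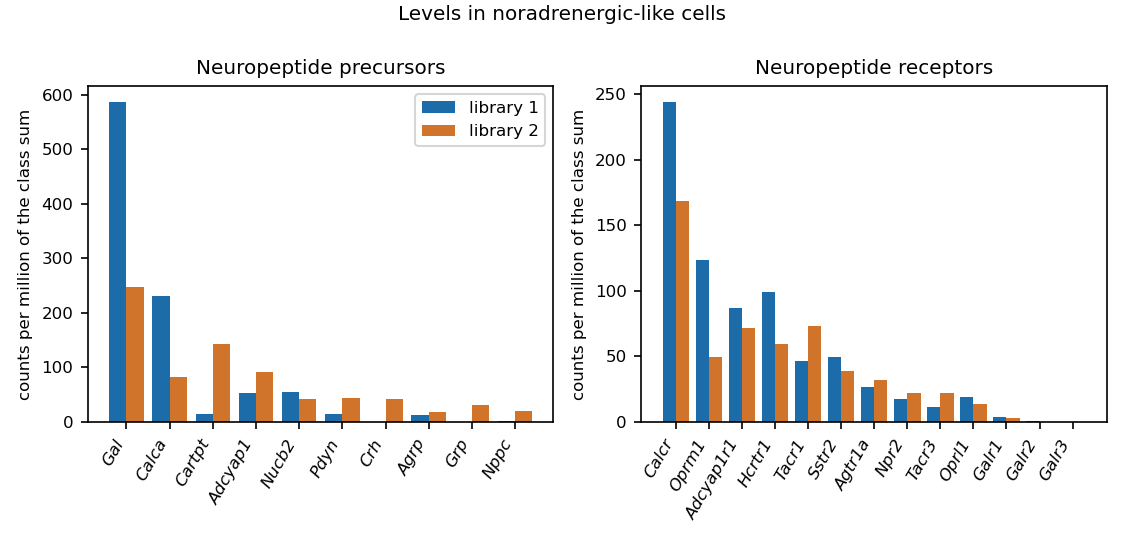
Level in CPM of the class sum (linear axis from 0) of the 10 neuropeptide precursors and 10 receptors of highest mean level in noradrenergic-like cells, with Galr1 to Galr3, 1 bar per library. Gal and Calcr lead, at means of 417 and 206 CPM, and Cartpt is low in library 1 (14.2 CPM) and high in library 2 (143 CPM).

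With every cell thinned to 1000 UMIs, Gal was seen in 5 of 12 noradrenergic-like cells of library 1 (41.7%, exact 95% interval 15.2 to 72.3) and 16 of 75 of library 2 (21.3%, 12.7 to 32.3). Oligodendrocyte-like cells, which should lack the gene, gave 0 of 37 and 0 of 520 at this depth, which allows shares of up to 8.11% and 0.58%. Before thinning, at medians of 83596.5 and 7813 UMIs, Gal was seen in 12 of 12 and 51 of 77 noradrenergic-like cells (66.2% in library 2), and in 1 of 37 and 1 of 657 oligodendrocyte-like cells at medians of 9760 and 1407 UMIs. The thinned share rose with depth, to 83.3% and 53.1% at 5000 UMIs, so cells without a Gal UMI were not shown to lack it. Thinned Calca was seen in 2 of 12 and 7 of 75 cells (9.33%), Cartpt in 0 of 12 and 10 of 75 (13.3%) and Calcr in 1 of 12 and 8 of 75 (10.7%, against 1.15% of oligodendrocyte-like cells in library 2). Galr1 was seen in none. Cells with Gal together with a further peptide were too few to set apart from independence: in library 2, 3 cells had Gal and Calca against 1.49 expected, 1 had Gal and Cartpt against 2.13, and 3 had Gal and Adcyap1 against 1.71. At 2000 UMIs the ratio of observed to expected was 1.02 for Calca, 0.622 for Cartpt and 0.721 for Adcyap1.

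Peptide and receptor genes were then placed by the class of their highest level among the named classes with at least 5 cells in each library. Unnamed neurons were not ranked, so a gene may stand higher in them. Of 55 precursors, 10 had the same highest class in both libraries at a mean of 20 CPM or more. For 5 of them it was noradrenergic-like cells: Gal, Cartpt, Pdyn, Calca and Nucb2. Cartpt and Pdyn each stood at 14.2 CPM in library 1. Gal reached 8.68 CPM in the next class, vascular or blood-like cells, from 1 UMI in each library. Agt led in astrocyte-like cells (556 CPM), Crh in excitatory-like neurons (50.2), Qrfp in ependymal-like cells (21.5), and Edn1 and Edn3 in vascular cells (44.5 and 54.9). Of 66 receptors, 22 had such a class. Oprm1, Sstr2, Calcr, Hcrtr1 and Agtr1a led in noradrenergic-like cells, and Adcyap1r1, Ntsr2 and Ednrb in astrocyte-like cells (124, 270 and 137 CPM). Crhr1 and Ramp3 led in granule-like neurons, Cckbr and Npy2r in ependymal-like cells, Trhr, Npr3 and Prlr in excitatory-like neurons, Cckar, Tacr3 and Npr2 in trigeminal-like neurons, and Calcrl, Ramp2 and Ednra in vascular cells. Galr1 was not among them: it stood at 13.8 and 6.78 CPM in excitatory-like neurons, 14.9 and 10.2 in inhibitory-like neurons, 0 and 16.4 in unnamed neurons, and 4.05 and 2.76 in noradrenergic-like cells. Of 9 adrenergic receptors, Adra2a led in noradrenergic-like cells (44.0 CPM, next 9.98 in astrocyte-like cells) and Adra1b in excitatory-like neurons (25.0).

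**Figure D4:**
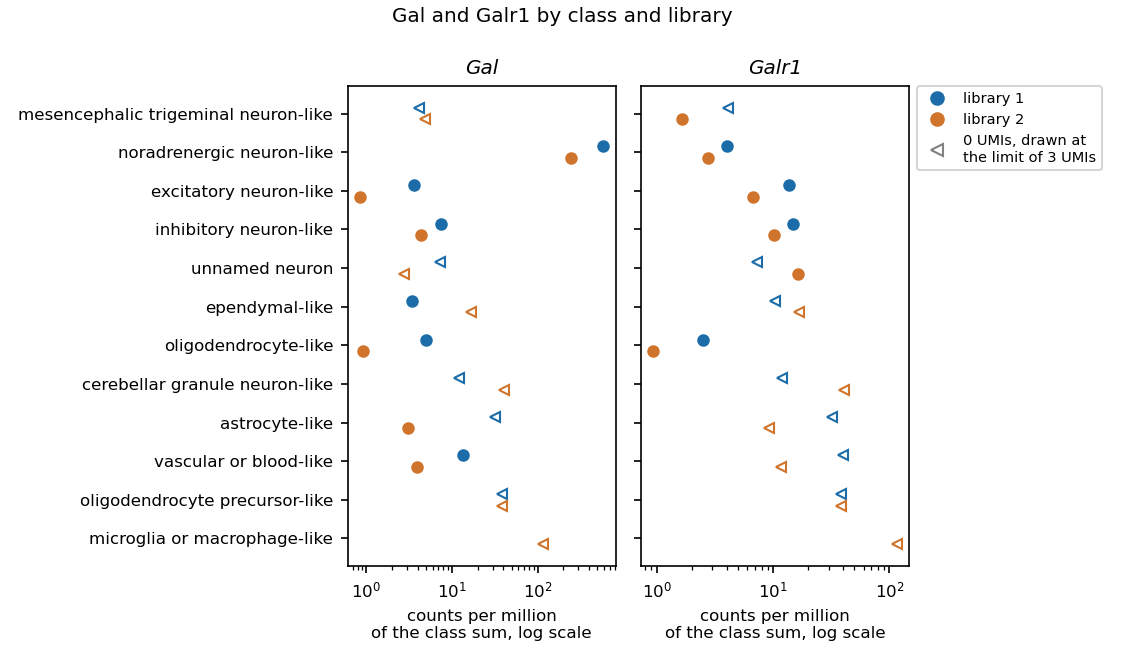
Level in CPM of the class sum (log axes) of Gal (left) and Galr1 (right) in each named class and in unnamed neurons, 1 point per library with at least 5 cells, with open triangles at the limit of 3 UMIs where no UMI was seen. Gal is highest in noradrenergic-like cells (587 and 247 CPM), and the highest measured level of Galr1 is 16.4 CPM, in unnamed neurons of library 2.

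Against all non-neuronal cells, the question was which genes, receptors above all, were neuronal in the same dissection. Of the named genes Slc10a4 rose most (6.92 ± 0.38, SE, n = 2, adjusted p 4.97e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gal followed (6.86 ± 0.35), then the transcription factor gene Tfap2b (6.48 ± 0.44), Fibcd1 (6.21), Calcr (5.76 ± 0.50), Cacng3 (5.72), Nxph4 (5.71) and Tmem35a (5.61); Pgr15l had a pooled ratio of 109 (36.6 to 531). No UMI was seen in the class of Tcf7l2, a factor of Wnt signalling in glia (at least 149-fold lower), Unc5cl (at least 121-fold), Cldn14 (at least 114-fold), the axonemal dynein gene Dnah3 (at least 100.3-fold), Pltp, Armc2, Frmpd2, Ak9, Spata17 or Slc24a4 (at least 81.0-fold to 57.2-fold). Library 1 and library 2 alone gave 6.19 and 5.93 for Slc10a4, 6.52 and 5.98 for Gal, 5.85 and 5.05 for Cacng3, and 6.01 and 4.85 for Tmem35a. Of 10143 genes tested, 2792 were higher and 2901 lower, 2389 and 2543 by at least 2-fold, and 99.98% of calls had the same sign in both libraries.

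In the lists of secretion and excitability more members rose than fell. Of 13 peptide processing and granin genes 11 rose and 1 fell, with Chgb at 4.38 ± 0.29, Scg2 at 3.84, Pcsk1n at 3.63 and Cadps at 1.24. Of 9 precursors 6 rose and 1, Agt, fell, with Calca at 5.41 ± 0.37 (5.18 and 4.42 in the libraries alone), Cartpt at 5.03 ± 0.47 and Adcyap1 at 4.29 ± 0.40. Of 15 receptors 9 rose and 5 fell (Ntsr2, Calcrl, Ramp1, Ednra and Ednrb), with Oprm1 at 5.24 ± 0.45 (4.94 and 3.91), Hcrtr1 at 5.24 ± 0.47 (5.11 and 3.95) and Adcyap1r1 at 1.52. Of 7 genes of tetrahydrobiopterin and monoamine metabolism 4 rose and none fell, with Maoa at 4.08 ± 0.26, Spr at 1.80, Gch1 at 1.39 and Qdpr at 1.19. Of 2 adrenergic receptors Adra2a rose (3.45 ± 0.44) and Adra1a did not pass (0.26, adjusted p 0.675 by edgeR). Of 8 GIRK channel and gap junction genes 6 rose and 2 fell, with Kcnj9 at 4.61 (4.02 and 3.90), Panx2 at 3.24, Kcnj6 at 3.17 and Kcnj3 at 1.97. Of 17 pacemaker and calcium channels 11 rose and 4 fell, with Cacna1a at 1.23, Cacna1c and Cacna1d at 1.08 and Kcnma1 at 0.92. Of 26 glutamate and GABA receptors 20 rose and 4 fell, with Grin2b at 3.43, Grin2a at 3.11, Gabrb1 at 0.94 and Gabbr1 at 0.82. Of 9 growth factors and receptors 5 rose and 3 fell, with Fgf13 at 5.08 ± 0.34, Vgf at 4.86 (4.42 and 4.23), Ntrk3 at 1.34 and Igf1r at -1.75. Of 8 transcription factors 3 rose and 3 fell, with Lmx1b at 2.28, Pbx3 at 0.70 and Ebf1 at -3.55. Of 11 dissociation response genes 7 fell and 1 rose, with Egr1 at -2.08, Fos at -1.33, Fosb at -1.25 and Jun at -0.70. The riser, Hspa1a, shares near-identical sequence with Hspa1b, so its counts are uncertain. Of 5 nuclear RNAs 4 fell and 1 rose, with Neat1 at -4.29, Malat1 at -1.70, Xist at -1.38 and Kcnq1ot1 at 0.79. The counts of all 12 lists were the same adjusted over the list alone.

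DESeq2 called 3189 genes in place of 5693 and ended the calls of Dnah3, Pltp, Ak9, Frmpd2, Armc2, Slc24a4, Spata17, Spr and Pbx3, and the fit without the replicate block ended that of Jun. Library 1 and library 2 alone moved the fold by over 1.5 times for Calcr (7.12 and 4.58), Cartpt (2.44 and 4.71), Fgf13 (5.81 and 4.50), Tfap2b (6.62 and 5.53), Fibcd1 (6.44 and 4.91), Spr (2.54 and 1.10), Panx2 (3.94 and 2.35), Grin2a (2.42 and 3.69), Lmx1b (1.12 and 3.15), Ebf1 (-2.55 and -4.88), Fosb (-1.95 and -0.56), Xist (-0.54 and -2.34) and Neat1 (-3.45 and -5.15).

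Inhibitory-like and excitatory-like neurons of the dissection were compared next. Zfpm2, a cofactor of GATA factors, was 3.69 ± 0.17 log2 units higher in inhibitory-like neurons (SE, n = 2, adjusted p 6.96e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Also higher were Megf11 (3.64 ± 0.25), the nuclear factor I genes Nfix (3.43 ± 0.28), Nfib (2.85 ± 0.19) and Nfia (2.29), St18 (3.30 ± 0.33), Sox2ot (2.39), the chromatin remodeller gene Chd7 (2.03), Zfp536 (1.97) and Cacna2d3 (1.97). Lower were the homeobox genes Lmx1b (-2.81 ± 0.30) and Lmx1a (-2.07), Pax5 (-2.58), Adamts2 (-2.54), Epb41l4a (-2.48), Abi3bp (-2.39), the prolactin receptor gene Prlr (-2.34 ± 0.28), Adcyap1 (-2.14 ± 0.32), the calcium channel subunit gene Cacna2d1 (-2.11 ± 0.15, adjusted p 3.94e-10 by edgeR) and Tmem163 (-2.02). Of 9012 genes tested, 148 were higher and 189 lower, 88 and 109 by at least 2-fold, each with the same sign in both libraries.

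Of 7 precursors, Pnoc rose (2.73 ± 0.51), Tac1 (-2.34 ± 0.38), Adcyap1 and Crh fell and 3 did not pass (1 and 3 adjusted over the list alone); Crh had 2 UMIs against 142, a pooled ratio of 0.0328 (0.0039 to 0.121). Of 15 receptors, 3 fell (5 adjusted over the list alone): Calcr (-2.89 ± 0.62), Prlr and Npr3 (-2.13). Galr1 did not pass (0.32 ± 0.51, adjusted p 0.865 by edgeR). Of 11 transcription factors 2 rose, the LIM homeobox genes Lhx5 (3.35 ± 0.40) and Lhx1 (3.05 ± 0.46), and 4 fell, among them Ebf2 (-1.04) and Zfhx3 (-0.86). Of 29 glutamate and GABA receptors 1 rose, Gria3 (0.54), and 8 fell (1 and 9 adjusted over the list alone), with Gabrb1 at -0.56, Grin2a at -0.54 and Grin2b at -0.53. Of 18 pacemaker and calcium channels 1 rose and 1 fell, Kcnq5 (-0.98). Of 10 growth factors and receptors Igf1r rose (0.64) and Bdnf (-1.25) and Ntrk3 (-0.62) fell (1 and 3 adjusted over the list alone). Single members fell in peptide processing (Scg2, -0.64, of 13; 5 adjusted over the list alone), adrenergic receptors (Adra1b, -2.58 ± 0.55, of 2) and the dissociation response (Fosb, -0.75, of 11). None of 4 genes of tetrahydrobiopterin and monoamine metabolism, 6 GIRK channel and gap junction genes or 5 nuclear RNAs passed (0, 0 and 1 adjusted over the list alone), with Maoa at -0.64, Kcnj6 at -0.29 and Kcnj3 at -0.09. The counts adjusted over the list alone were otherwise the same.

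DESeq2 called 38 genes in place of 337, and of the 41 named genes it kept Zfpm2, Megf11, Nfix, Nfib, St18, Sox2ot, Cacna2d3, Lmx1b, Epb41l4a, Prlr, Cacna2d1, Crh, Kcnq5, Zfhx3, Lhx5 and Lhx1; of these the call of Zfhx3 ended with all classes in the fit and Crh turned to 6.64 where clusters came from highly variable genes. With library 1 and library 2 alone the folds moved by over 1.5 times for Nfix (4.31 and 2.70), Nfia (3.31 and 1.37), Chd7 (2.72 and 1.44), Pax5 (-3.82 and -1.86), Adamts2 (-3.55 and -1.90), Abi3bp (-3.80 and -1.73), Lmx1a (-2.86 and -1.46), Tmem163 (-2.98 and -1.46), Pnoc (3.08 and 0.97), Tac1 (-3.06 and -1.38), Npr3 (-3.05 and -1.13), Calcr (-1.73 and -3.60), St18 (3.55 and 2.68), Lhx1 (3.03 and 2.36) and Adra1b (-2.70 and -1.87).

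Within the noradrenergic-like class, cells were split at the median of Gal per 10000 UMIs in each library, to ask what goes with galanin. The value is a continuous one, and 1 galanin-high and 2 galanin-low cells of library 1 and 6 of each in library 2 lay within a factor of 1.2 of the split, while 26 of the 39 galanin-low cells of library 2 had no Gal UMI. Summed over cells, galanin-low cells also held the class markers Slc6a2 and Dbh at a lower CPM in both libraries, without a call for either. The split therefore does not set galanin apart from the level of these markers. Galanin-high cells had more of the serotonin receptor gene Htr2c (1.52 ± 0.34 log2 units, SE, n = 2, adjusted p 0.00304 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Agtr1a (2.16 ± 0.56), Id4 (1.20), Tmem50b (1.18), Qdpr (1.01 ± 0.22), Asb4 (0.99), Calca (0.96 ± 0.25, adjusted p 0.017) and Shisa6 (0.83). They had less of the phospholipase gene Plcb1 (-2.30 ± 0.41, adjusted p 4.95e-05 by edgeR), Bcl2l11 (-2.01), the sodium channel gene Scn9a (-1.89), Zfp804b (-1.87 ± 0.26, adjusted p 1.3e-09), Srrm4 (-1.55), Ptprk (-1.50), Cntnap5b (-1.27), Pcdh7 (-1.24), Il1rapl1 (-1.24) and Gabrg3 (-1.14). Of 6292 genes tested with Gal left out, 10 were higher and 36 lower, 7 and 26 by at least 2-fold, and 39 of the 46 had the same sign in both libraries. The 36 lower genes were long, with a median of 473.4 kb against 59.0 kb in random lists matched on level.

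Few list members passed. Of 6 precursors only Calca rose (1 adjusted over the list alone), with Adcyap1 at 0.66 (adjusted p 0.581 by edgeR) and Cartpt at -0.21 (adjusted p 0.938). Of 7 receptors only Agtr1a rose (4 adjusted over the list alone), with Calcr at 0.53 (adjusted p 0.4 by edgeR). Of 6 genes of tetrahydrobiopterin and monoamine metabolism Qdpr rose (2 adjusted over the list alone). Of 14 pacemaker and calcium channels Kcnd2 fell (-1.05; 2 adjusted over the list alone). Of 23 glutamate and GABA receptors Gria1 fell (-1.05 ± 0.21, adjusted p 0.000563 by edgeR; 1 adjusted over the list alone), and of 9 dissociation response genes Atf3 fell (-1.68 ± 0.42; 5 adjusted over the list alone). None passed among 13 peptide processing and granin genes, 2 adrenergic receptors, 5 GIRK channel and gap junction genes, 8 growth factors and receptors, 4 transcription factors and 4 nuclear RNAs (1 nuclear RNA rose adjusted over the list alone). In library 1 a galanin-low cell held 42 UMIs of Gad2, a marker of inhibitory neurons with a median of 0 in these cells, and without this cell 9 of the 46 calls were left, Htr2c and Plcb1 among them. Without it Zfp804b stood at -0.51 ± 0.31 (adjusted p 0.751 by edgeR) and Gria1 at -0.55 ± 0.23 (adjusted p 0.513). Of the 11 other library 1 cells, left out singly, 3 also left only 4 to 12 calls.

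None of the 21 named genes was called by DESeq2 (0 calls, 37 genes at an unadjusted p under 0.05), without the replicate block (0 calls, 178 at an unadjusted p under 0.05) or in cells with at least 500 genes (1 call). Kcnd2 was -1.44 in library 1 and 0.10 in library 2, and most others were larger in library 1 (Htr2c 1.66 and 0.92, Plcb1 -2.33 and -1.61, Bcl2l11 -2.67 and -1.03, Scn9a -2.86 and -0.76, Zfp804b -2.81 and -0.72, Ptprk -1.91 and -0.53, Cntnap5b -1.82 and -0.57, Pcdh7 -2.08 and -0.19, Il1rapl1 -1.88 and -0.44, Gabrg3 -1.84 and -0.37, Atf3 -2.94 and -0.88), with Id4 the other way (0.46 and 2.99).

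The libraries themselves were compared within classes, with no test since each batch holds 1 library. In noradrenergic-like cells, 6 of 9 precursors with at least 20 UMIs were lower in library 1 than in library 2 (median log2 ratio of the 9 -0.76, percentile 0.01 of matched random lists), while Gal (1.23), Calca (1.43) and Nucb2 (0.39) were higher. Precursors went the other way in excitatory-like (0.25), inhibitory-like (1.59, from 3 genes) and all cells (0.12). Lower as well were dissociation response genes (-0.66) and mitochondrial genes (-0.71), both at percentile 0.0. Nuclear RNAs (0.68, percentile 98.99), tetrahydrobiopterin genes (0.37, 98.47) and receptors (0.32, 97.86) were higher, and the median over all genes was -0.01. The nuclear RNAs were 4 genes, of which Malat1 was lower and Xist (138.7 against 51.0 CPM) follows sex, whose cell counts differed between the libraries. Nuclear RNAs were lower in library 1 in astrocyte-like (-0.40) and all cells (-0.45), and receptors in inhibitory-like neurons (-0.79). Dissociation response genes went the other way in excitatory-like (0.38), inhibitory-like (0.65) and astrocyte-like cells (2.22) and the same way in oligodendrocyte-like cells (-0.51). In astrocyte-like cells Egr1, an immediate early gene, stood at 1633 CPM in library 1 and 114 in library 2 and Fos at 505 and 70.6. Mitochondrial genes were lower in library 1 in astrocyte-like (-1.33), oligodendrocyte-like (-0.55) and all cells (-0.66). Malat1, an RNA kept in the nucleus, had 7803 and 12003 CPM in noradrenergic-like cells. The labels do not say whether the libraries differed in protocol, mice or handling.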

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

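The tests of free RNA in the other neurons and of Slc18a2, and the test and setting that left out 1 cell of library 1, were chosen only after the result was seen, and no biological explanation was tested for any pattern, since the design gives no groups to compare.

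Barcodes left out by the filters or as doublets carried noradrenergic transcripts above the limit that a count of 0 allows. The 10 such barcodes of library 1 (74966 UMIs, limit 40.02 CPM) held Slc6a2 at 93.38 CPM, Dbh at 80.04 and Slc18a2 at 53.36. The 119 of library 2 (458333 UMIs, limit 6.55 CPM) held Slc6a2 at 183.27 CPM, Dbh at 106.91, Slc18a2 at 124.36 and Gal at 19.64.

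Noradrenergic transcripts also appeared in kept cells outside the class, with Slc6a2 at 10.56 and 21.74 CPM in non-neuronal cells of libraries 1 and 2 against 2893 and 2009 in noradrenergic-like cells. Noradrenergic cells misplaced by the clustering were argued against by the 28 cells of library 1 outside the class with UMIs of 3 markers, which held Slc6a2 at 0.73% of the level in the class. Free RNA may account for Slc6a2 and Dbh in non-neuronal cells, where their ratio was 0.8 in library 1 (0.274 to 2.251, class 0.492) and 0.711 in library 2 (0.437 to 1.144, class 0.563), and where Slc6a2 differed by at most 2.84 times between oligodendrocyte-like, astrocyte-like and ependymal-like cells. Free RNA from noradrenergic cells was argued against as the only source of Slc18a2, a vesicular transporter gene shared with other amine cells. The ratio of Slc18a2 to Slc6a2 was 3.4 in library 1 (1.642 to 7.716, class 1.268) and 2.533 in library 2 (1.779 to 3.662, class 1.369). A further source stays open, and free RNA from other cells was not tested. In the other neurons free RNA from noradrenergic cells cannot be told apart from expression of their own. There the ratio of Dbh to Slc6a2 lay above that of the class in library 1 (1.08, 0.68 to 1.71) and around it in library 2 (0.652, 0.397 to 1.056).

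Between galanin-high and galanin-low cells, 46 genes were called, 36 of them lower in galanin-high cells. Random splits of the cells within libraries rarely gave as many: 2 of 100, the real one included. The highest of the others had 57 calls and the median was 7. Since random splits gave calls as well, the adjusted p values of single genes in this comparison are too small. Single cells of library 1 moved the real count: 9 calls were left without the galanin-low cell that held Gad2. Leaving out 3 other cells singly left 4 to 12. The splits were not repeated for these smaller counts, so a random grouping was argued against for the count of 46 only. A galanin-low library 1 cell that also carries Gad2 was argued against as the only cause, since the 46 folds kept a median of 86.5% (76 to 95.5) without it, against 101.5% (88.6 to 110) without each of 11 other library 1 cells. It stays open for the 8 genes that kept under 50%, such as Zfp804b (-1.87 ± 0.26 to -0.51 ± 0.31), while 20 of the 37 calls that ended kept over 80%, such as Agtr1a (2.16 ± 0.56 to 2.00 ± 0.57), of which 2 fell under the low-count filter and 8 ended by the adjustment alone, at an unadjusted p no larger than that of a call before. Gene length stays open as a candidate explanation: the median length of the 36 genes lay at percentile 100 of matched random lists, and the 629 shortest genes had a median log2 fold of 0.12 (0.16 and 0.12 in libraries 1 and 2) against -0.15 for the 629 longest (-0.16 and -0.11). Genes called in the random splits were as long (508.0 kb, 920 calls), so long genes were called more often whatever the split, and the pattern stays unsettled.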

How the results depend on the processing

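Tests on trigeminal-like neurons and on the cluster holding Nps, thinning to 5000 UMIs, and the settings without trigeminal and granule neurons and without the Gad2 cell were chosen after the data were seen. Noradrenergic-like cells against other neurons kept a count within 1.5 times of 3844 under 11 alternatives (2727 with no replicate block to 4197 without trigeminal and granule neurons), and against non-neuronal cells within 1.5 times of 5693 under 11 (5264 with no replicate block to 6134 with no low-count filter). DESeq2 called 1266 and 3189 genes there, each among the original calls and in the same direction, 38 of 337 between inhibitory-like and excitatory-like neurons, 0 of 46 between galanin-high and galanin-low cells (37 at an unadjusted p under 0.05), 1698 of 4454 for trigeminal-like neurons and 94 of 445 for the cluster holding Nps. It estimates a spread per gene, and the cause of its lower counts was not tested. With no replicate block the last 4 counts were 128, 0 (178 at an unadjusted p under 0.05), 3868 and 129. All classes in the fit gave 2489 genes against other neurons, with fewer genes tested (8577), 158 for inhibitory-like neurons and 8 for galanin; a class defined by 3 markers gave 2167 and Leiden resolution 0.5 gave 531 for inhibitory-like neurons, where other cells enter the classes. The galanin count was 1 with at least 500 genes, 2 with at most 10% mitochondrial UMIs, 20 with 2 times the doublets removed and 9 without the Gad2 cell (1 galanin-low cell of library 1), where the folds kept a median of 86.5%. For the other counts the cause was not tested. The galanin count was 42 to 46 under the remaining 6 alternatives, and that of inhibitory-like neurons 273 to 454 under the remaining 8. Highly variable genes turned Crh in inhibitory-like neurons to 6.64 and kept 114 of the 337 calls; the cause was not tested. Leaving out 1 library leaves 1 library, so no count of calls was possible. The log2 ratios ran from -1.44 to 0.10 for Kcnd2 between galanin-high and galanin-low cells. They ran from -0.05 to 1.26 for Tac1 in trigeminal-like neurons and from -2.95 to 7.31 for Nps in its cluster. For other called named genes the ratio of a library alone kept its sign but lay further from the fit than the SD of the 2 library ratios. Without libraries 1 and 2, these were 17 and 15 of 56 genes against other neurons and 26 and 19 of 62 against non-neuronal cells. For inhibitory-like neurons they were 8 and 3 of 41, and for galanin 4 and 2 of 21. The Gal level (416.98 CPM) ran from 246.87 to 587.08 with a library left out and was 265.99 in cells defined by 3 markers. Depth sets the share of cells with Gal: 83.33% in library 1 at 5000 UMIs, and 9.09%, 37.84% and 53.12% in library 2 at 500, 2000 and 5000 UMIs. In library 2 neurons were 49.65% of cells with at least 500 genes, a filter that removes shallow cells, and 42.55% with highly variable genes, and noradrenergic-like cells were 2.17% at most 10% mitochondrial UMIs, with fewer of them kept. Of 128 other class shares under 6 alternatives, 34 left their counting intervals, 10 of them with highly variable genes, 8 with at least 500 genes and 7 at Leiden resolution 0.5, where excitatory-like neurons were 22.34% of library 2 (9.79 to 12.19).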

Other observations

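The comparisons of trigeminal-like neurons and of the cluster holding Nps, and the tests on Cartpt, were all chosen after the data were seen.

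Mesencephalic trigeminal-like neurons (11 and 39 cells), the other large neurons of the dissection, were compared as well. Against the remaining neurons with the noradrenergic-like class left out, Ppp1r1c rose by 6.53 ± 0.32 log2 units (SE, n = 2), the annexin gene Anxa2 by 6.47, the Wnt effector gene Lef1 by 6.47, Pirt, a partner of sensory ion channels, by 5.94, Runx1 by 5.81 and Lcp1 by 5.50, while Smpx had a pooled ratio of 122 (40.4 to 605). The nerve growth factor receptor gene Ngfr (4.96), Fgf1 (3.61), Tacr3 (3.29) and Cckar (3.29) also rose. Receptors for fast transmitters were low: of 30 glutamate and GABA receptors 1 rose and 24 fell, and of 17 neuropeptide receptors 2 rose and 14 fell, among them Galr1 with a pooled ratio of 0.0691 (0.0017 to 0.399). No UMI was seen of Rtl4, Col25a1, Trpc5 or Penk (at least 65.3-fold, 58.4-fold, 54.5-fold and 39.2-fold lower). Of 19 pacemaker and calcium channels, 2 rose and 14 fell. Atf3, a gene that responds to nerve injury and to dissociation, stood at 137.4 and 54.4 CPM against 8.4 and 8.2 in the other neurons. In all, 2156 genes were higher and 2298 lower among 11075 by edgeR's quasi-likelihood test; DESeq2 called 1698, and Rtl4, Col25a1, Penk and Galr1 were not among them. Library 1 and library 2 alone gave 7.87 and 4.63 for Runx1, 5.54 and 5.17 for Pirt, 6.55 and 5.84 for Ppp1r1c, 6.54 and 5.79 for Anxa2, 6.35 and 5.46 for Lef1, 3.79 and 4.19 for Ngfr and 3.79 and 2.54 for Atf3.

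An unnamed neuronal cluster (15 and 83 cells) was picked for Nps, the gene of neuropeptide S, but its identity was not settled. Calb1 and Car8, both Purkinje markers here, were among its leading genes, and 14 and 75 of its cells took the name of Purkinje neurons with at least 500 genes, 11 and 53 at Leiden resolution 2.0, while all took that of excitatory neurons at 0.5. Within the cluster only library 1, with 15 of the cells, held the transcript: 356.6 CPM there and 0 in library 2, against 1.2 and 7.6 in the other neurons. The cluster shared other genes in both libraries. Gpc3 rose by 3.62 log2 units (4.30 and 2.93 in libraries 1 and 2 alone), Itpr1 by 2.92 (1.89 and 3.59), the thyrotropin-releasing hormone receptor gene Trhr by 2.32, Tacr1 by 2.26 and Ebf2 by 1.89. The enkephalin gene Penk (1.43) and Sst (1.46) rose, and Crh, with no UMI in the cluster, was at least 3.89-fold lower. Among 10930 genes 186 were higher and 259 lower by edgeR's quasi-likelihood test. DESeq2 called 94 and ended the calls of Nps and Sst, and those of Sst and Crh ended with no replicate block.

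Cartpt stood at 14.2 CPM in noradrenergic-like cells of library 1 and at 143.4 in those of library 2, 10.1 times higher. Free RNA as the source was argued against, since the other neurons of library 2 held Cartpt at 3.42% of the level in the class. A few rich cells were argued against as well: the 3 cells with the most held 28.85% of the 104 UMIs, 34 cells had at least 1, and without those 3 the level was 108.2 CPM, 7.62 times that of library 1. A difference in mice, in the part of the nucleus dissected or in protocol stays open and cannot be examined with 1 library per batch.

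Cells with Xist and cells with Y-linked transcripts were found in each library, and the labels give both sexes. Among noradrenergic-like cells of library 1, 7 had Xist alone, 2 Y-linked transcripts alone and 3 both; in library 2 the numbers were 13, 48 and 2, with 14 cells having neither. Among other neurons they were 53, 99 and 12 in library 1 and 159, 388 and 16 in library 2, and among non-neuronal cells 21, 51 and 10, and 273, 277 and 8.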
